A study of Drosophila melanogaster with 3 samples.

How the data were processed

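The measurements were anti-GFP ChIP-seq peak lists from whole Drosophila melanogaster embryos, 0 to 24 h old and of mixed sex, that expressed Pdp1 with a C-terminal eGFP. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp, and 3 biological replicates of 1 technical replicate each were made from the same fly line. Replicate numbers were taken from the labels. The series held 1 group, so no comparison between conditions, no pairing and no batch test could be made. Replicates 1, 2 and 3 came with no date or sequencing run in the sources used here.

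The deposited lists were in narrowPeak format on the dm6 and dm3 assemblies, 5 lists per assembly. Per the deposited file records, peaks of each replicate and of the pooled replicates were called against a control alignment as relaxed lists meant as input for IDR, a test of whether peaks rank alike in replicates. The optimal lists were derived by the authors from these. The aligner, the peak caller and the IDR version are not given in the sources used here. The deposited signal value of each peak is the authors' own measure from the caller, relative to a control, with a scale that differed between lists, so it served to describe and rank peaks within a list. The deposited −log10 q values were capped, with 13361 optimal lines sharing 4.43, and were described but not tested. Summit positions came from the lists. An interval can hold several summits, each on a line of its own and each counted as a peak here. Such summits can match the same replicate line and are not independent in the tests over peaks. Every line of the dm6 optimal list was checked and found among the 13583 strongest lines of the pooled list, so the optimal list is the top of the pooled ranking. Each relaxed list held 30000 lines, which is a limit on its length and says nothing of depth. No read counts were in the lists, so depth per replicate was unknown; median signals of the dm6 replicate lists were 86.1, 37.8 and 26.8. The binomial intervals given cover counting of peaks only. Control libraries and signal tracks were not analysed here.

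Gene models were those of Ensembl release 115 for the Release 6 assembly (BDGP 6.54), and sequence came from the Release 6 genome. None of the 133565 dm6 intervals on arms 2L, 2R, 3L, 3R, 4 and X ended past an arm end of this genome, and all 13583 dm6 optimal peaks lay on these arms. Coordinates are 1-based. The dm3 lists were used for counts and overlaps alone, and no coordinates were converted.

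Peaks were taken as shared when summits lay within 200 bp, and replicates were compared over their N strongest peaks by signal, with N the 13583 optimal peaks. Overlaps and promoter shares were compared with 200 random placements on the same arm. Each summit was assigned to the TSS window (within 1 kb of a TSS of a protein-coding gene) and otherwise to the 5' UTR, coding exon, 3' UTR, intron or intergenic class. For named peaks the annotation at the summit itself is given, which can belong to a neighbouring or overlapping gene. Motifs were searched on both strands within 50 bp of the summit and in a window of the same width centred 300 bp away, on alternating sides along the list. The windows were compared by an exact two-sided sign test over peaks with the motif in 1 window alone, with p-values below 1.0e-300 set to that value. All words of 8 bases found in at least 20 windows were tested in the same way. P-values were adjusted by the Benjamini-Hochberg method (BH) over 11 motifs, over all words and over 15 gene lists.

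A gene was called bound when an optimal summit lay within 1 kb of a TSS of it. Each list was compared with 10000 random lists of protein-coding genes of the same size, drawn within 10 classes of gene length. The random lists were not matched on the number of TSSs per gene, and a gene with more TSSs has more chances to be called bound. Genes were drawn singly, so neighbouring genes of a list were treated as independent. The lists were the circadian clock, muscle, fat body and lipid storage, insulin and TOR signalling, bZIP factors, gut and Malpighian tubule, nervous system, epidermis and trachea, embryo patterning, haemocytes, and, by symbol pattern, cytosolic ribosomal proteins, chemoreceptors, eggshell proteins, cytochrome P450 enzymes and glutathione S-transferases. In the insulin and TOR list 17 of 18 symbols were matched and Tor was not. Genes can be in several lists: srp is in 3, and Pdp1 is in the clock and bZIP lists. The groups, tests, gene lists, motifs and naming rule, and the alternatives other than those listed as added below, were fixed before the data were examined.

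Genes were named by a rule fixed at the same time. It took the genes with the TSS nearest to the 20 strongest optimal peaks found in all 3 replicates (peaks within 1 kb counted once), all members of the clock list, Tm1, Tm2 and Mef2, up to 4 bound genes of highest signal from each other list, and the Pdp1 locus with 5 kb on each side. The pattern TTRYRYAA, the word TTATATAA, the 100 kb window at Pdp1 and the gene families under the other observations were chosen after the data were seen.

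The alternatives covered the overlap distance, the number of peaks compared, the genome build, a stricter peak set, each replicate left out in turn, the TSS window, the annotation, the motif, its window and its control, and the assignment of peaks to genes. For locations, motifs and genes, leaving out a replicate kept the optimal peaks found among the strongest of both others. The optimal list was not remade and still drew on all 3 replicates, so the left-out replicate kept its part in the choice of peaks. Added after the data were seen were local placements, rankings by single replicates, peaks with TTRYRYAA alone, and lists without Pdp1 or without 3 genes that the symbol patterns took in but that encode other proteins.

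The procedures were tested on simulated data. With no motif planted, the sign test over 13583 peaks gave p = 0.116 (exact) and 0 of 27172 words passed. With TTACGTAA, a form of TTAYGTAA, planted in 1358 simulated peaks, 100% of planted copies were found, with a difference of 9.75 percentage points between windows. The copies were placed wholly inside the summit window, so the share found checks the search code alone. Of 1000 random lists of 20 genes, each compared with 1000 further lists, 2% had p under 0.05, and of 200 lists with 17 of 20 genes bound, 100% did. With 69.4% of summits kept, and moved by less than the 200 bp allowed for a match, 71.4% were found as shared. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.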

Results

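Genomic binding of Pdp1 was measured by ChIP-seq in whole Drosophila melanogaster embryos of both sexes collected 0 to 24 h after laying. Pdp1 is a transcription factor of the PAR bZIP class, which carries a basic leucine zipper next to a region rich in proline and acidic residues, and it is known as an activator of Clk in the circadian clock and as a regulator of muscle genes. The flies carried Pdp1 fused at its C-terminus to eGFP, a green fluorescent protein, and chromatin was precipitated with an antibody against GFP. The series held 1 group of 3 biological replicates, each from a biological sample of its own, and no second condition, so the comparisons were made between replicates, between peaks and chance positions, and between groups of genes. The deposited values were peak lists, with 30000 lines per replicate, 30000 lines from the pooled replicates, and 13583 optimal peaks retained by the authors' test of irreproducible discovery rate (IDR). The lists carried no read counts, so sequencing depth was unknown. P-values taken over peaks or genes measured variation between peaks or genes, not between replicates.

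The peak of highest signal lay at the promoter of Pdp1 itself, the tagged gene, where extra copies on the transgene were not excluded as a source of signal. This peak, at 3L 7867031 to 7867949 of the dm6 assembly, had a deposited signal of 11903, and its summit was intergenic, 260 bp upstream of a Pdp1 transcription start site (TSS). It ranked 1 in replicate 1, 6 in replicate 2 and 1 in replicate 3. The reference sequence within 25 bp of the summit, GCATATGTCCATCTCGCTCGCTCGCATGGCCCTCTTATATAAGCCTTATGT, held the word TTATATAA, and TTAYGTAA, the canonical PAR bZIP site, lay within 50 bp. Signal here is the authors' own value per peak and was used to describe and rank peaks within a list.

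The peaks next in strength lay at genes of varied function. The peak ranked 2, at 3L 1341916 to 1342775, was 21 bp upstream of the TSS of indra, which encodes a zinc finger protein, and its summit sequence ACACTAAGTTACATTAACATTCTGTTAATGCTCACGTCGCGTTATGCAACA held TTATGCAA. The peak ranked 3, at 3L 7808580 to 7810246, was 82 bp upstream of CG32369 and also lay within 5 kb of the 3' end of Pdp1. The peak ranked 4, at 3R 16242149 to 16243043, was in an intron 156 bp upstream of a TSS of tara, which encodes a transcriptional co-regulator with a role in sleep, and its summit sequence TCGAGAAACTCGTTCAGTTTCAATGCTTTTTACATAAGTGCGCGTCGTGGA held TTACATAA. CG12054, ETHR, the receptor for ecdysis triggering hormone, cbt, which encodes a zinc finger transcription factor, CG10336, CG14100 and larp, which encodes an RNA-binding protein, followed at ranks 5 to 10. The remaining genes of the 20 named peaks were Ugalt, a UDP-galactose transporter, Idh, an isocitrate dehydrogenase, Hibch, an enzyme of valine breakdown, Pp2C1, a protein phosphatase, Alas, which makes the first intermediate of haem, Lk6, a kinase of a translation initiation factor, mRpS10, a mitochondrial ribosomal protein, CG2059, CG9147 and Mic26-27, a component of the complex that shapes mitochondrial cristae. Of these 20 peaks, which were found in all 3 replicates and had signals from 5039 to 11903, 18 had a summit within 1 kb of a TSS. The exceptions were cbt, with its summit in an intron 1362 bp upstream, and Pp2C1, with its summit in an intron 2148 bp downstream. TTAYGTAA lay within 50 bp of the summit at 2 of the 20, Pdp1 and tara, and the wider form TTRYRYAA at 11 of them.

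Peaks across the Pdp1 gene were dense. The gene spans 3L 7811458 to 7867369 on the minus strand, and 40 optimal summits lay in it or within 5 kb of it. Of these, 27 were found in all 3 replicates, 3 lay within 1 kb of 1 of the 4 annotated TSSs, and 5 had TTAYGTAA within 50 bp. Besides the promoter peak and the summit ranked 3, strong summits stood within the same interval as the latter (summit 7808945, signal 3406), 873 bp upstream of a further TSS in an intron (7856052 to 7856650, signal 2863), in the 3' UTR (7811481 to 7811983, signal 2413) and in other introns (7850704 to 7851690, signal 2391, and 7842522 to 7842976, signal 2115). A 100 kb window over the gene, 7780001 to 7880000, held 52 optimal summits, against a median of 9 over 13331 such windows and at most 47 in any window that did not overlap it. Some of these summits share an interval, as at 7807243 to 7808384 and 7808580 to 7810246, so the window held fewer intervals than summits. The window was chosen after its values were seen.

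**Figure D1:**
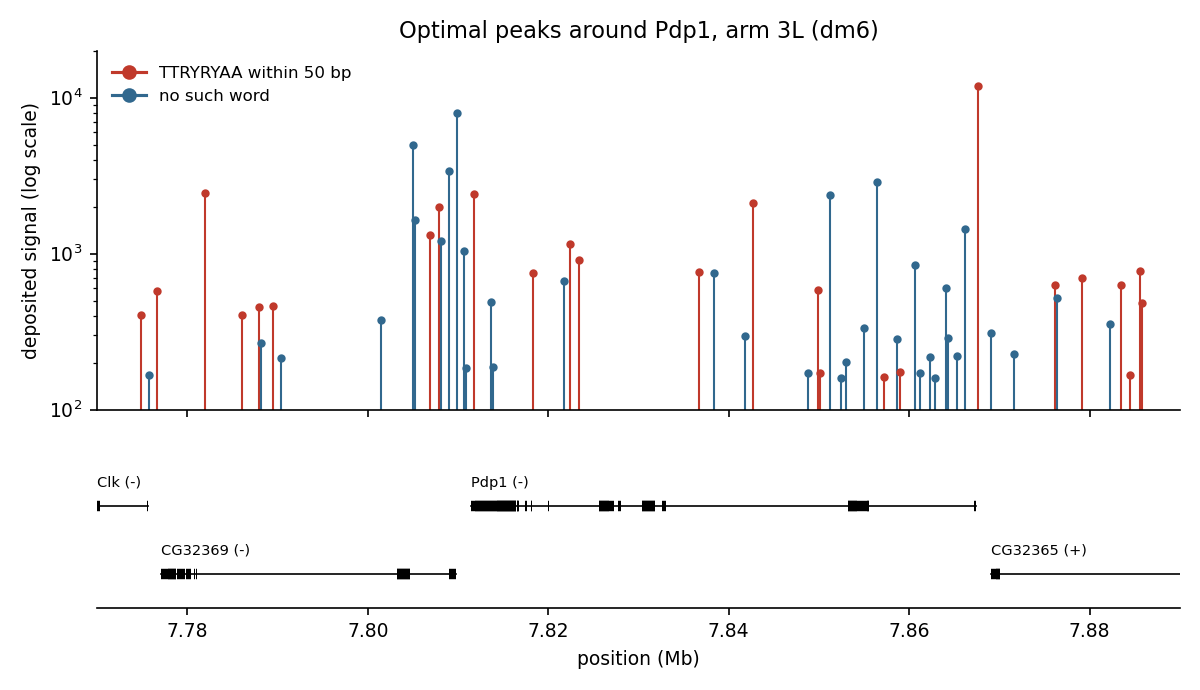
Each vertical line is an optimal summit on arm 3L (x axis, position in Mb, dm6), its height the deposited signal on a log axis, red where TTRYRYAA lay within 50 bp and blue where it did not; the lower tracks show genes with exons as boxes. The tallest line, at 11903, stands just upstream of the Pdp1 gene, which runs right to left.

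Binding was spread over all 6 chromosome arms. The 13583 optimal peaks, with a median width of 362 bp, gave 101.2 peaks per Mb on arms 2L, 2R, 3L and 3R together, 104 per Mb on X and 80.9 per Mb on chromosome 4. Strong sites were found in all replicates more often than weak ones. Of the 1358 strongest optimal peaks, 98.6% were among the 13583 strongest peaks of each of the 3 replicates, within 200 bp of a summit, against 4.86% of the 1358 weakest. The latter share was set in part by the limit on peaks per replicate, since the whole lists of replicates 1, 2 and 3 held 98.2%, 93.4% and 94.6% of the optimal peaks. Across the whole optimal list 60.6% (8226 peaks) were found in all 3 replicates, and 49 peaks in none. The share found per replicate was 89.3% in replicate 1, 76.3% in replicate 2 and 79.2% in replicate 3, with a mean of 81.6% ± 6.84 (SD, n = 3). The share in all 3 depended on how many peaks were taken per replicate, and was 28.6% with N/2 peaks and 87.9% with whole lists.

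Pairs of replicates shared 72.0% ± 3.52 (SD over 3 pairs) of their 13583 strongest peaks, with 68.0% between replicates 1 and 2, 74.5% between 1 and 3 and 73.5% between 2 and 3. None of 200 random placements on the same arms shared as many (mean 3.88%, one-sided permutation p = 0.00498, the smallest that 200 placements can give). The ranks of peaks also differed between replicates. Across optimal peaks, which are not independent replicates, Spearman's rho of the peak signals was 0.436 between replicates 1 and 2, 0.606 between 1 and 3 and 0.706 between 2 and 3 (mean 0.583 ± 0.136, SD over 3 pairs). The pooled signal followed replicate 1 most closely (rho 0.880) and replicates 2 and 3 less (0.682 and 0.753).

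Promoters were the favoured location. Summits of 6919 optimal peaks, 50.9% (95% Wilson interval 50.1 to 51.8), lay within 1 kb of the TSS of a protein-coding gene, against 20.3% ± 0.353 (SD) of 200 random placements on the same arm (one-sided permutation p = 0.00498, the smallest possible). The strongest peaks of each replicate gave 48.8%, 53.9% and 55.8%, a mean of 52.8% ± 3.62 (SD, n = 3), so the excess was larger than the spread between replicates. Of the summits farther from a TSS, most were in introns, 33.1% of all summits against 36.4% at random, or intergenic, 12.2% against 28.2%. Coding exons held 0.707% against 10.7% at random, and 3' UTRs 2.80% against 3.87%. These are shares of all summits, and the larger TSS class among peaks leaves less for every other class. The lower intron share therefore does not show that introns were avoided among summits farther from a TSS. Promoter peaks were also more frequent among strong peaks, with 71.9% of the strongest 1358 and 42.6% of the weakest 1359 near a TSS. With a window of 250 bp in place of 1 kb the promoter share was 31.1%, against 6.27% at random. Placements within 50 kb of each peak, a control chosen after the data were seen, reached 27.5% at promoters and 17.1% in intergenic sequence.

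**Figure D2:**
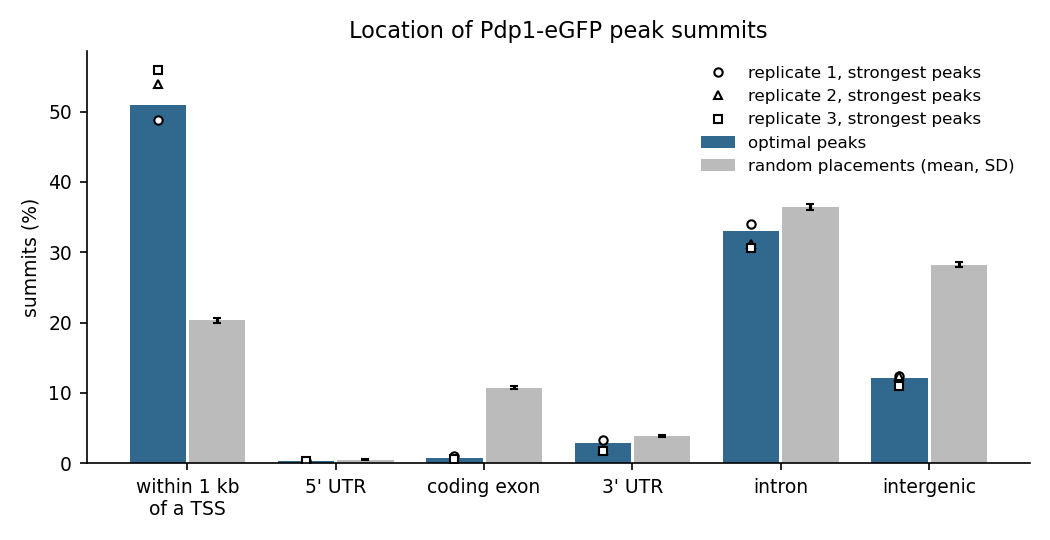
Bars give the percentage of optimal summits (blue) and of random placements (grey, mean with SD over 200) per annotation class, and open symbols the strongest peaks of each replicate. The class within 1 kb of a TSS holds 50.9% of optimal summits and 20.3% of random ones.

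The PAR bZIP site stood at the summits. TTAYGTAA lay within 50 bp of the summit at 1627 optimal peaks, 11.98% (95% Wilson interval 11.4 to 12.5), and in 107 windows of the same width centred 300 bp away, 0.788%, a ratio of 15.2 (exact two-sided sign test over peaks, p at or below 1.0e-300, BH-adjusted over 11 motifs 1.1e-299). Among the strongest peaks of each replicate it was at 14.6% in replicate 1, 6.07% in replicate 2 and 6.43% in replicate 3, a mean of 9.04% ± 4.82 (SD, n = 3) against 0.923% ± 0.0977 in the windows 300 bp away. Among the 1644 peaks with the centre of a site within 50 bp of the summit, a limit that caps the value, the median distance was 14 bp. The site was more frequent at peaks farther than 1 kb from a TSS, 15.8%, than at promoter peaks, 8.34% (odds ratio 2.06, two-sided Fisher exact test, p = 9.96e-41). Over the 13583 strongest peaks of replicates 1, 2 and 3 the distal shares were again higher (19.1%, 7.25% and 8.14% against 9.92%, 5.07% and 5.09% at promoters). Among the 1000 strongest the distal share was higher in replicate 1 (25.7% against 23.4%) but lower in replicate 2 (4.41% against 7.503%) and replicate 3 (10.98% against 14.9%), differences that were not tested. The ratio of summits to windows 300 bp away changed with the definition, from 6.90 with windows of 100 bp each side to 50.9 for the longer word RTTAYGTAAY.

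Motifs of some other factors were also more frequent at summits. TATCGATA, the DNA replication-related element (DRE) of housekeeping promoters, was at 1.91% of summits and 0.567% of windows 300 bp away (ratio 3.38, exact sign test, adjusted p = 1.3e-23), with 3.54% at promoter peaks and 0.225% at distal peaks. By the same exact test the C/EBP word TTGCGCAA had a ratio of 5.88 (adjusted p = 1.2e-21), the GATA word WGATAAG 1.43 (1.9e-09), the E-box CAGCTG 1.30 (2.7e-06) and the CRE word TGACGTCA 1.73 (0.0336). TTGCGCAA is itself of the form TTRYRYAA, so its peaks are also counted in the shares given for that form. The remaining 5 motifs tested, the AP-1 site, CACGTG of CLK and CYC, the GAGA element, the Zelda site and the MEF2 site, had ratios from 0.894 to 1.04 and adjusted p-values of 0.452 or more.

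Without a motif given in advance, words of the form TTRYRYAA led the list. Of 26323 words of 8 bases tested, 808 were more frequent at summits than 300 bp away and 413 less frequent (exact sign test, BH-adjusted p under 0.05). TTACATAA, which is TTATGTAA on the other strand, ranked first and was at 9.53% of summits against 0.655% (ratio 14.6), and TTATATAA ranked second with 8.58% against 0.574% (ratio 14.9). TTACGTAA had the highest ratio of the family, 18.6, followed among the others by TTACGCAA with 11.7 and TTATGCAA with 6.95. Of the 10 words of this form 9 passed, and TTGTACAA did not (ratio 1.22, exact sign test, adjusted p = 0.840). Taken as 1 pattern, a choice made after the words were seen, TTRYRYAA was at 35.8% of summits (4861 peaks) and 4.90% of windows 300 bp away, with 26.1% at promoter peaks and 45.9% at distal peaks.

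**Figure D3:**
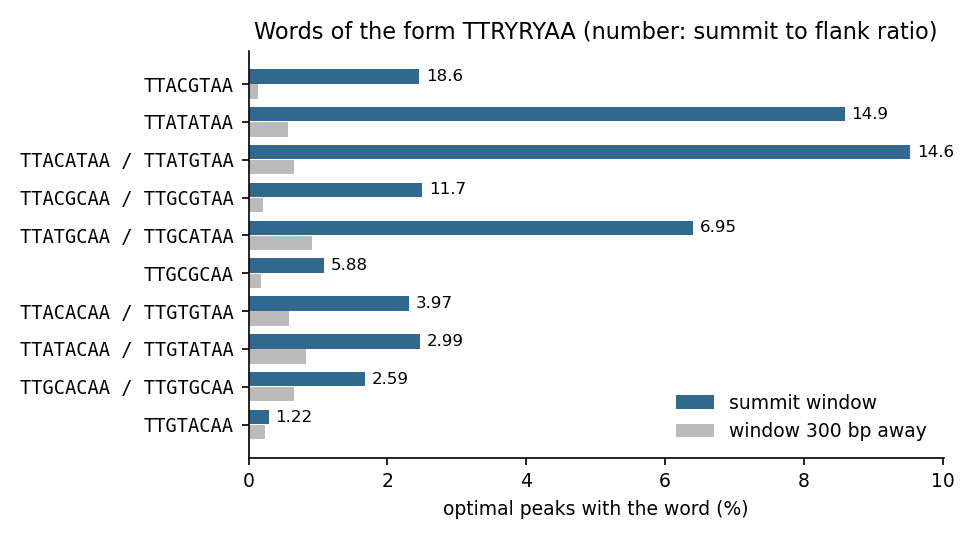
Bars give the percentage of optimal peaks with each word of the form TTRYRYAA within 50 bp of the summit (blue) and in the window 300 bp away (grey), with both strands merged and the ratio printed beside each pair. TTACGTAA has the highest ratio, 18.6, and TTGTACAA the lowest, 1.22.

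Strong peaks had the site more often than weak ones in the pooled ranking. TTAYGTAA was at 17.2% of the 1358 strongest optimal peaks (234 peaks) and at 6.85% of the 1358 weakest (93 peaks; odds ratio 2.83, two-sided Fisher exact test, p = 5.6e-17). This direction depended on the replicate that set the ranking. Ordering the same optimal peaks by the signal of a single replicate, a test added after the data were seen, gave an odds ratio of 50.2 with replicate 1 but the opposite direction with replicate 2 (0.245, 7.26% against 24.2%) and replicate 3 (0.528, 13.5% against 22.9%). Within each replicate's whole list of 30000 lines the strongest 10% again had the site more often than the weakest 10%, with odds ratios of 17.1, 1.97 and 3.93. These relaxed lists of replicates 1, 2 and 3 reach down to −log10 q values of 0.225, 0.188 and 0.476, so their weakest lines can be background. The comparison therefore does not isolate strength among peaks.

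Replicate 1 differed from replicates 2 and 3 in the sequence under its peaks. The 2595 peaks among the strongest 13583 of replicate 1 alone had TTRYRYAA at 71.4% of summits, and 27.2% of them lay within 1 kb of a TSS. The 1648 peaks among the strongest of replicates 2 and 3 but not of replicate 1 had it at 9.16%, against 4.85% in windows 300 bp away, and 59.4% lay within 1 kb of a TSS. The 8302 peaks among the strongest of all 3 replicates, counted in replicate 1, had it at 32.0%.

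**Figure D4:**
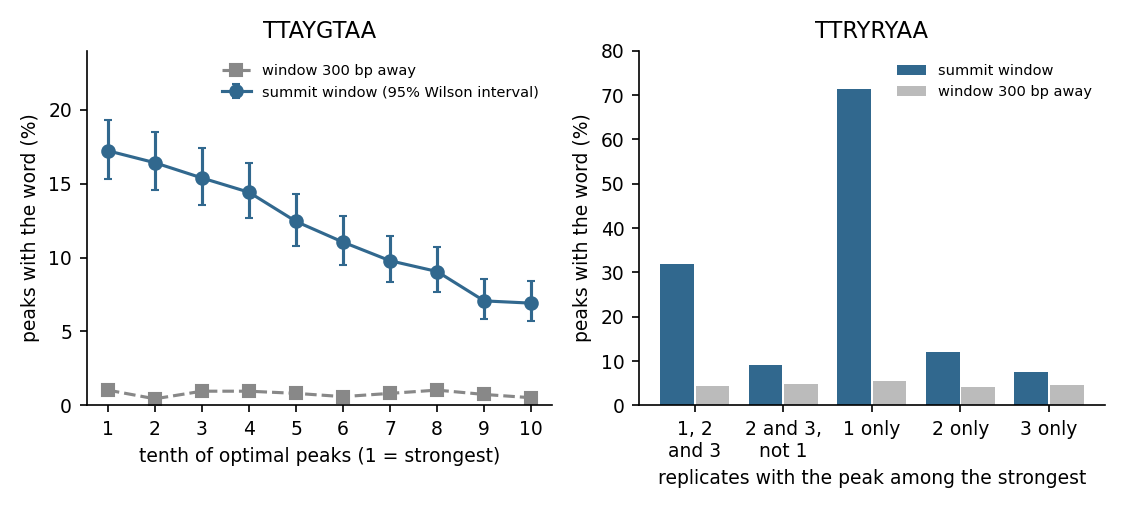
Left, the percentage of optimal peaks with TTAYGTAA in each of 10 groups by pooled signal, at the summit (blue, 95% Wilson interval) and 300 bp away (grey); right, the percentage with TTRYRYAA at the summit (blue) and 300 bp away (grey) for peaks among the strongest of the replicates named. The left share falls from 17.2% in the strongest group to 6.92% in the weakest, and on the right the peaks of replicate 1 alone reach 71.4%.

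An optimal summit within 1 kb of a TSS was present at 6148 of 13945 protein-coding genes (44.1%), which are called bound here, and 15 gene lists were compared with 10000 random lists of the same size and gene length (two-sided empirical permutation p, BH-adjusted over the 15 lists). The circadian clock list, which includes Pdp1, had 12 of 17 genes bound against 9.38 by chance, a difference that did not pass (ratio 1.28, adjusted permutation p = 0.374). Its strongest peaks after that of Pdp1 were at slmb, an F-box protein of PER turnover (3R 21127397 to 21128123, rank 168), sgg, a GSK3-type kinase (rank 704), and vri, the bZIP repressor of Clk (2L 5304980 to 5305764, in an intron 160 bp upstream of a TSS, rank 891). Clk, the activator at the centre of the loop, had 3 summits near a TSS. The strongest, with TTAYGTAA (rank 3210), was intergenic at 3L 7776447 to 7776732, 981 bp upstream. When replicate 1 or replicate 3 was left out, 1 of the 3 was among the strongest peaks of both other replicates. Clk (3L 7763233 to 7775603) lies near Pdp1 (3L 7811458 to 7867369). The extent of the transgene was unknown, so extra copies were not excluded as a source of signal at Clk either. Peaks at dco, tim, cwo, CkIIbeta, jet, cyc and nmo ranked from 1783 to 11848. The peaks named for all 12 bound genes were found in all 3 replicates. The 5 unbound genes were per, with its nearest optimal summit 1532 bp from a TSS, Pdf (5439 bp), Pdfr (6631 bp), cry (13524 bp) and CkIIalpha (48487 bp).

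Muscle genes were bound more often than chance, with 22 of 27 against 14.8 expected (ratio 1.48, adjusted permutation p = 0.0160). Tm1, a tropomyosin gene, had 5 summits near a TSS, the strongest in the 5' UTR at 3R 15278397 to 15278829 (rank 691), and its neighbour Tm2 had 2 (3R 15310024 to 15310211, intergenic, rank 6380), with 1 left without replicate 2 or 3. Mef2, a main regulator of muscle differentiation, had 4, the strongest in an intron 62 bp upstream of a TSS at 2R 9929516 to 9929966 (rank 2308), and 2 remained without replicate 3. The highest signals of the list besides that of Tm1 were at mew, an integrin alpha subunit, with TTAYGTAA at the summit (rank 226), Mlc2, a myosin light chain (rank 633), Mhc, the muscle myosin heavy chain (rank 865), and Msp300, a nuclear anchoring protein (rank 1019). Without replicate 1 the ratio was 1.51 (adjusted permutation p = 0.0605), and for peaks found in all 3 replicates 1.54 (0.0595), so the ratio was no lower with these smaller sets of peaks. It fell to 1.24 with summits anywhere in the gene or within 1 kb (adjusted permutation p = 0.165) and to 1.31 with a TSS window of 500 bp (0.247), and rose to 2.74 with peaks that had TTRYRYAA alone, an alternative chosen after the data were seen (0.0030). The list missed the threshold under 4 of 12 alternatives, with a range from 0.0015 to 0.247.

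Genes of bZIP factors, Pdp1 among them, were bound at 16 of 19 loci against 9.43 expected (ratio 1.70, adjusted permutation p = 0.0066), led after Pdp1 by CrebB (rank 257), Atf3 (rank 273) and REPTOR (rank 694). Without Pdp1, an alternative chosen after the data were seen, the ratio was 1.69 (adjusted permutation p = 0.0144). Assigning each summit to its nearest TSS alone ended this call (adjusted permutation p = 0.0760; range over 12 alternatives 0.0018 to 0.707). Cytosolic ribosomal protein genes had the largest excess of the 15 lists, with 80 of 92 bound against 33.4 expected (ratio 2.39, adjusted permutation p = 7.5e-04, from a raw p of 2.0e-04, the smallest that 10000 lists can give). RpL32 (rank 108), RpL13 (rank 175) and RpL10Ab (rank 432) led it, together with RpLP0-like (rank 385), which the symbol pattern took in although it encodes another protein. The summit ranked 432 was 968 bp upstream of RpL10Ab, in the 5' UTR of another gene, and a further summit lay 36 bp from a TSS of RpL10Ab. The 111 promoter peaks of the ribosomal protein list had TTRYRYAA at 10.8% of summits, against 26.3% of other promoter peaks (two-sided Fisher exact test, p = 1.1e-04), and the DRE word at 12.6% against 3.39%. Counting peaks with TTRYRYAA alone, an alternative chosen after the data were seen, neither list passed (ribosomal proteins, ratio 1.10, adjusted permutation p = 0.931; bZIP factors, ratio 1.43, adjusted permutation p = 0.707; lowest over the 12 alternatives 7.5e-04 and 0.0018).

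Insulin and TOR signalling genes had 14 of 17 bound against 8.999 expected (ratio 1.56, adjusted permutation p = 0.0463). The list was led by Pdk1, a kinase that activates Akt (rank 976), Pi3K92E, a catalytic lipid kinase subunit (rank 1454), InR, the insulin receptor (rank 2182), and Tsc1, an inhibitor of TOR signalling (rank 2496). This call did not hold under 8 of 12 alternatives, among them leaving out replicate 1 (ratio 1.43, adjusted permutation p = 0.230) or replicate 3 (ratio 1.59, adjusted permutation p = 0.102), with a range from 0.0081 to 0.931.

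The nervous system, chemoreceptor and P450 lists were bound less often than chance. Of 20 nervous system genes 2 were bound against 11.1 expected (ratio 0.180, adjusted permutation p = 7.5e-04), elav, an RNA-binding protein of neurons, with a peak 272 bp upstream of a TSS (rank 622), and Gad1, which makes the transmitter GABA (rank 5850). The ratio was 0.506 with summits in the gene or within 1 kb and 0.412 with nearest-TSS assignment. Chemoreceptor genes had 12 of 179 bound against 75.2 expected (ratio 0.160, adjusted permutation p = 7.5e-04), with the strongest peaks near Ir60b (rank 130) and Or88a (rank 1036), and near Or7a (rank 3251) and Gr64f (rank 2835) in 2 replicates each. This ratio ranged from 0.0773 without replicate 1 to 0.345 with peaks that had TTRYRYAA alone, and was 0.341 with nearest-TSS assignment. Of 85 cytochrome P450 genes 20 were bound against 39.3 expected (ratio 0.508, adjusted permutation p = 7.5e-04), with Cyp6a22 (rank 773), Cyp6u1 (rank 889) and Cyp4ae1 (rank 1171), and with Cyp1 (rank 111), which encodes a cyclophilin. The P450 call ended with nearest-TSS assignment (ratio 0.887, adjusted permutation p = 0.566). With peaks that had TTRYRYAA alone the P450 (ratio 0.673, adjusted permutation p = 0.672) and nervous system (ratio 0.482, adjusted permutation p = 0.690) calls ended, though both ratios stayed below expectation. Over 12 alternatives the lowest adjusted permutation p of both lists was 7.5e-04.

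The other 7 lists did not pass. Glutathione S-transferases had 18 of 35 bound against 12.4 expected (adjusted permutation p = 0.130, and 0.0450 without replicate 2, in a range from 0.0216 to 0.578), with GstE13 (rank 238), GstE9 (rank 656), GstE14 (rank 886) and GstE5 (rank 1370) the strongest. Fat body and lipid storage genes had 12 of 19 against 10.1 (adjusted permutation p = 0.559), led by Lpin, mdy, ACC and SREBP, which act in lipid synthesis, at ranks 303 to 2225. Gut and Malpighian tubule genes had 6 of 13 against 6.95 (adjusted permutation p = 0.806), with peaks at the transcription factor genes fkh, srp, grn and GATAe. Haemocyte genes had 5 of 12 against 6.76 (adjusted permutation p = 0.538), with srp, ush and drpr, and with Col4a1 in 1 replicate. Epidermis and trachea genes had 5 of 13 against 7.35 (adjusted permutation p = 0.374), with verm in 3 replicates and mmy, obst-A and grh in 2. The ratio of 0.680 fell to 0.318 without replicate 1 (adjusted permutation p = 0.0630) and 0.311 with a TSS window of 500 bp (0.0553). With nearest-TSS assignment it rose to 1.05. Embryo patterning genes had 8 of 24 against 12.5 (adjusted permutation p = 0.161), with the strongest peaks at Antp, found in 2 replicates, Abd-B, hry and Ubx. This list passed in 1 of 12 alternatives, the stronger part of the optimal list (ratio 0.350, adjusted permutation p = 0.0446). Its ratio ranged up to 1.16, with nearest-TSS assignment. Eggshell genes had 2 of 16 against 5.32 (adjusted permutation p = 0.161), Cp18, found in 2 replicates, and Cp190, which encodes an insulator protein rather than an eggshell component. The ratio of 0.376 became 0.227 without replicate 1 (adjusted permutation p = 0.120) and 0.210 without the 3 genes that encode other proteins (0.0825). The list passed in 1 of 12 alternatives, random lists not matched on length (ratio 0.283, adjusted permutation p = 0.0322). Its ratio ranged from 0.210 to 0.645.

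**Figure D5:**
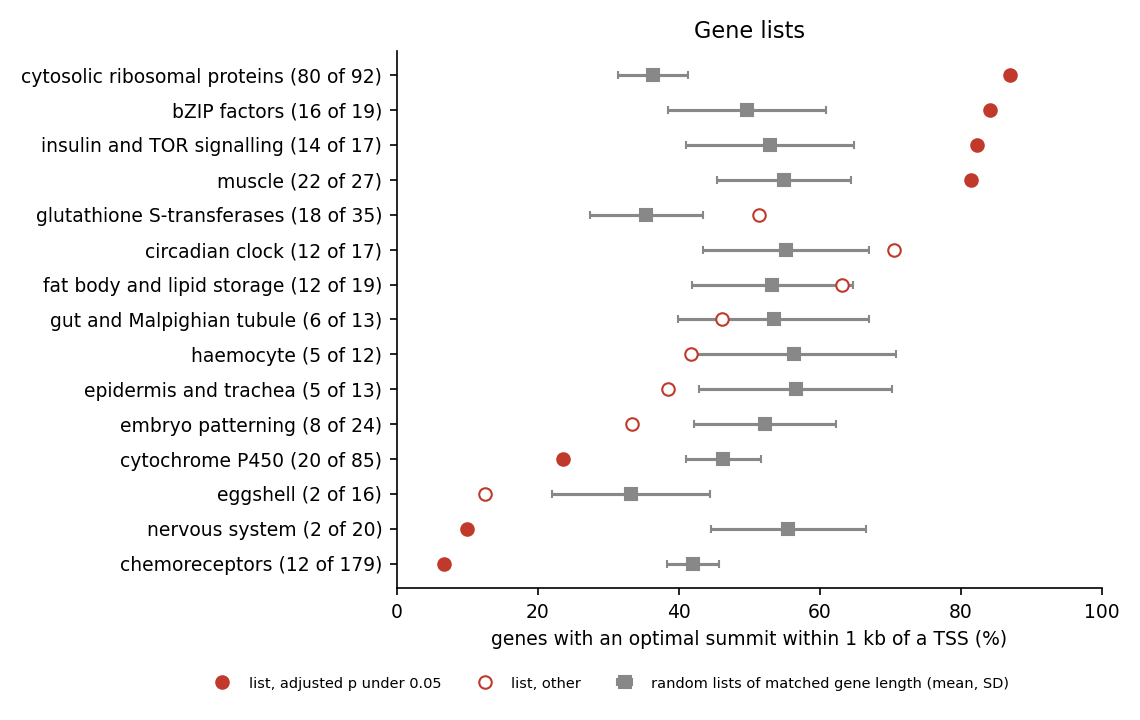
Circles give the percentage of each list's genes with an optimal summit within 1 kb of a TSS, filled where the adjusted p was under 0.05, and grey squares the mean and SD of 10000 random lists of matched gene length. Cytosolic ribosomal proteins (80 of 92) stand highest and chemoreceptors (12 of 179) lowest.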

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

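The sign test in this part was chosen after the lists had been seen. A PAR bZIP signal was present in lines that the comparisons above do not use. Among the 16410 pooled lines on the arms that fell below the optimal list, 572 had TTAYGTAA within 50 bp of the summit, 3.49% against 0.689% (113 lines) in windows 300 bp away (exact two-sided sign test, p = 1.74e-75). The wider form TTRYRYAA was at 15.4% of these summits and 4.53% of the windows 300 bp away.

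On the dm3 assembly 25 of 13709 optimal peaks lay on scaffolds other than the 6 arms. Their best rank was 379 and their median rank 7230. Where they fall on dm6 was not tested, since no coordinates were converted.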

How the results depend on the processing

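The rankings by single replicates, the peaks with TTRYRYAA alone, TTATATAA and TTRYRYAA as motifs, local placements and the lists with genes removed were tests chosen after the data were seen. Of 75 recomputed main results, 63 kept their direction and their side of the threshold or stayed within the spread, 10 moved and 2 reversed. The promoter excess held in all its alternatives. With each replicate left out in turn, the optimal peaks found in both remaining replicates gave shares from 55.2% to 57.4%. The excess of TTAYGTAA at summits held in all its alternatives, with ratios from 6.90 to 50.9. Words passing numbered 1205 with random placements as control, and 638 words passed under both controls. Stricter sets leave 6791 peaks (stronger part of the list) or 8226 peaks (found in all 3 replicates) by construction. The share of optimal peaks found in all replicates was 44.7% with summits within 50 bp, 28.6% with N/2 peaks, 86.6% with 2N peaks and 87.9% with whole lists, which follows from the stricter or looser definitions. With a replicate left out it ranged from 67.0% to 71.7%, since fewer replicates must hold the peak, and the rank correlation ranged from 0.436 to 0.706, the values of the single pairs.

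The relation of TTAYGTAA to peak strength reversed when the optimal peaks were ordered by replicate 2 (odds ratio 0.245) or replicate 3 (0.528) and was 50.2 with replicate 1. Part of this may follow from construction, since peaks enter the optimal list by their pooled signal and a ranking by 1 replicate is then made within a selected set. Whole lists, which are not selected by pooled signal, gave 17.1, 1.97 and 3.93 for replicates 1, 2 and 3. Their weakest lines can be background, so these values do not decide how the site relates to strength among peaks.

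The number of gene lists past the threshold was 4 with nearest-TSS assignment and 2 with peaks that had TTRYRYAA alone, against 7, and 5 to 8 with the other alternatives; the cause was not tested. Of 180 recomputed list results 158 kept their side of the threshold, 18 lost it and 4 gained it, and none of those that had passed reversed. Of the 12 alternatives per list, chemoreceptors passed in 12, ribosomal proteins and the nervous system in 11, bZIP factors and P450 genes in 10, muscle in 8 and insulin and TOR signalling in 4. Of 420 recomputed gene results 381 kept the presence or absence of a peak near a TSS and 39 changed it, among them Antp, Col4a1, Cp18, Gr64f, Or7a, grh and obst-A. With a replicate left out, these lost their peak because it was not among the strongest of both replicates that remained. No paired analysis was possible because there is 1 group. Depth was unknown, so its effect on the differences between replicates could not be measured.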

Other observations

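The gene families in this part and the tests of extra copies, of many regulatory elements, of sequence rich in A and T, of ribosomal proteins, of the number of peaks compared and of TTATATAA within single replicates were chosen after the results were seen; the tests of TATA boxes, of a weaker site and of weaker enrichment were set before the values they measure. Of 6 families of genes for mitochondrial proteins, 5 passed the threshold with more genes bound than expected from genes of the same length. An optimal summit lay within 1 kb of a TSS at 72 of 73 mitochondrial ribosomal protein genes, all but mRpS18A, against 22.5 expected (adjusted permutation p = 8.7e-04 over 13 families), with mRpS10 (rank 17), mRpL48 (rank 44) and mRpL54 (rank 51) the strongest; mRpL48, mRpL54 and mRpS18A were chosen after their values were seen. Respiratory complex I had 33 of 40 genes bound against 14.4, and ATP synthase 11 of 15 against 5.30, with median peak ranks of 872 and 390.5. Cytochrome c oxidase had 12 of 16 against 5.36 and the mitochondrial import machinery 12 of 15 against 5.57 (adjusted permutation p from 8.7e-04 to 0.0095 for these 4 families). The cytochrome bc1 complex, with 6 of 9 bound against 2.92, did not pass (adjusted permutation p = 0.0842). Its unbound genes, named after the values were seen, were UQCR-14L, UQCR-11L and UQCR-6.4L. With peaks found in all 3 replicates 6 of its genes were bound against 2.17 (unadjusted permutation p = 0.0128). Peaks with TTRYRYAA alone gave 5 against 0.983 (unadjusted permutation p = 0.0038), so the family was no clear exception. With peaks that had TTRYRYAA alone, 33 mitochondrial ribosomal protein genes were bound against 8.15 expected and 23 complex I genes against 4.94 (permutation p = 2.0e-04 for each, the smallest possible).

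Rab GTPase genes, which direct membrane traffic, were bound at 23 of 31 against 14.4 (adjusted permutation p = 0.0037), while proteasome (23 of 48 against 18.1), vacuolar ATPase (17 of 33 against 13.9) and translation initiation factor genes (22 of 44 against 19.9) did not pass. Cuticle protein genes (15 of 116 against 39.5), odorant-binding protein genes (6 of 51 against 15.7) and Jonah protease genes (0 of 16 against 4.89) were bound less often than chance (adjusted permutation p = 8.7e-04, 0.0035 and 0.0091). With peaks that had TTRYRYAA alone these 4 differences did not pass: Rab GTPases 5 against 4.83 (permutation p = 1), cuticle 10 against 13.8 (0.341), odorant-binding 5 against 5.77 (0.952) and Jonah 0 against 1.88 (0.273). Expected counts were lower with these fewer peaks, so the test had less power. For the Jonah genes a deficit could not have passed, since 0 is the lowest count possible. The random lists drew genes singly over the genome, whereas genes of a family can lie side by side. Such neighbours are not independent, which the permutation p-values do not allow for.

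Whether the promoter peaks of mitochondrial ribosomal protein genes form at PAR bZIP sites stays open. TTRYRYAA was at 38.2% of their 102 peaks and at 26.2% of 6706 promoter peaks at neither kind of ribosomal protein gene (odds ratio 1.75, two-sided Fisher exact test, p = 0.00877), a comparison made after both shares had been seen. The difference from the 111 peaks at cytosolic ribosomal protein genes (10.8%, two-sided Fisher exact test, p = 4.32e-06) decides nothing, since those have the word less often than other promoter peaks. Most peaks of the mitochondrial group lacked such a word, those of mRpS10 and mRpL48 included.

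The lower share of PAR bZIP words in replicates 2 and 3 than in replicate 1 is the first pattern. The number of peaks compared did not account for all of it. Among the 1000 strongest peaks TTAYGTAA was at 24.1% in replicate 1, 6.80% in replicate 2 and 13.9% in replicate 3. The nearest interval bounds were 5.37 percentage points apart. Over the 13583 strongest peaks the shares were 14.6%, 6.07% and 6.43%, so a part played by the number compared is not excluded. Weaker enrichment in replicates 2 and 3, with more of their strongest peaks at regions without a site, stays open. Peaks strong in both of them but not in replicate 1 had TTRYRYAA at 9.16% of summits, against 32.0% for peaks strong in all 3 (two-sided Fisher exact test, p = 1.87e-93), but shares of 23.7% and 22.9% over all strongest peaks of replicates 2 and 3 already place their remaining peaks below 32.0%, so this decides nothing. No table measures enrichment or depth per replicate, so the cause stays open, and no biological explanation was tested, since the design has 1 group.

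The 52 optimal summits in the 100 kb around Pdp1 are the second pattern. A high density of regulatory elements stays open. Of its 80 pooled lines 65.0% were optimal, a share that 26 of 2651 windows with at least 40 lines reached (0.981%), but the window was picked by its optimal count, so this share decides nothing. Extra copies of the region on the tagged transgene could raise all of its fragments and stay open, since the sources used here do not give the extent of the transgene. The share of its peaks with TTRYRYAA was 36.5% against 47.0% for matched peaks elsewhere (two-sided permutation p = 0.159), a difference that did not pass.

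The word TTATATAA, with a ratio of 14.9 between summits and windows 300 bp away, is the third pattern; TATA boxes of core promoters are argued against, since 11 of 1166 summit copies (0.943%) lay 15 to 50 bp upstream of a TSS. Sequence rich in A and T is argued against as well, since of 42 other words of the same bases the highest ratio was 4.89, for ATTATATA, which is TTATATA with an A before it. A weaker form of the PAR bZIP site bound by the tagged protein is a candidate explanation: among peaks without another TTRYRYAA word, TTATATAA was at 13.3% of the 981 strongest and 5.20% of the 981 weakest (two-sided Fisher exact test, p = 6.63e-10). Whole lists of replicates 1, 2 and 3, whose weakest lines can be background, gave odds ratios of 21.4, 1.21 (two-sided Fisher exact test, p = 0.302) and 2.86. Optimal peaks ordered by replicates 1, 2 and 3 gave 78.3, 0.0932 and 0.153, so the relation to strength depended on the replicate and this explanation is not settled.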
